A study of Mus musculus with 6 samples.

How the data were processed

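Gene expression was measured in 6 mouse brain tumours, 3 of each of 2 genotypes, with an Illumina bead array of the mouse transcriptome. Per the labels and the series' design text, cells of the genotype Olig2cre/+;p53fl/fl;hEGFRvIII or Olig2cre/cre;p53fl/fl;hEGFRvIII were transplanted into SCID mice, and the tumours were taken when the animals became neurologically ill. The 2 groups are called Olig2_het and Olig2_null below. Per the labels' protocols, RNA was extracted with Trizol, cleaned and treated with DNase on RNeasy columns and checked on a Bioanalyser, and the arrays were hybridised with cRNA labelled with biotin by an Ambion MessageAmp kit. The labels give tumours of the same number the same age, 45, 50 and 47 days for numbers 1, 2 and 3. They do not say whether the tumours of a genotype came from separate cell lines, so p-values measure the spread between these tumours.

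The authors deposited a table of signal intensity per probe on a linear scale, with no normalization between arrays, and beside each signal a detection p-value, per the file headers. It held 25697 probes. The lowest signals per array lay between 118.8 and 130.4, so no background had been subtracted. The median signal per array ran from 182.6 to 210.0, and between 13715 and 14811 probes per array had a detection p-value under 0.05. A second table from the authors held intensity values with a median of 193.8 in each of its columns. Each of its columns equalled the quantile-normalized signal of 1 array within 0.1% at every probe, so its scale is linear, it is not centred, and it holds no ratio. In 4 of the 6 columns the matching array had another replicate number of the same genotype: numbers 1 and 3 were exchanged in both groups. The groups are not affected, and arrays are numbered here as in the table of signals. Which of the ages 45 and 47 days belongs to numbers 1 and 3 is therefore uncertain. The scanner software and any slide or scan batch are not given in the sources used here.

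The signals were background-corrected with the normexp model, with the negative controls inferred from the detection p-values, an offset of 16 was added, and the arrays were quantile-normalized and put on a log2 scale (neqc in limma 3.58.1, R 4.3.3). The 14606 probes with a detection p-value under 0.05 on at least 3 of the 6 arrays were tested. For each probe a linear model with genotype as its only term was fitted with lmFit and eBayes in limma, two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all tested probes with a threshold of 0.05. Differences are Olig2_null minus Olig2_het on the log2 scale, with the moderated standard error (SE) of the fit. The number of arrays limits the precision.

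Where a probe was not detected on any array of a group, that group's level is a bound. The fold is then given as "at least", from the brighter group's mean against the other group's mean of, per array, the lowest normalized signal of any detected probe or the probe's own, whichever was higher. Where a probe was detected on only some arrays of a group, the measured fold is given with that number of arrays, and also with each undetected value raised to the lowest signal of any detected probe on its array.

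Probes were named from the platform's annotation, in which 23978 probes had 1 gene symbol, 0 had several and 1719 were unnamed here. Of the named probes, 23962 were matched by gene identifier to current symbols of the GRCm38.p6 annotation, which was used for names only because the sources used here name no build. A gene with several tested probes was represented by the one with the highest mean over the 6 arrays. In all, 9998 genes were tested. Trp53, 1 of 4 genes to be named whatever their result, is not analysed here.

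Before the data were examined, 35 gene lists for cell types, glioma classes and pathways were fixed from textbook knowledge, and the 31 lists with at least 5 measured members were tested with camera in limma, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over lists. Camera with an estimated correlation and fry were run beside it. The genes to be named were also set then: Olig2, Egfr and Pdgfra, the 10 largest rises and 10 largest falls among representative probes past the threshold with no overlap between the groups, passing over predicted and clone names, and up to 4 members past the threshold per list described, or up to 2 with the smallest p where none passed. Genes outside that rule are said to have been chosen later.

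The procedure was tested on simulated data. In 14606 simulated probes with the spread of the real ones, 200 were shifted in the simulated Olig2_null group. Of those shifted by a log2 difference of 1, 0% were called, of those shifted by 2, 52.2%, and of those shifted by 4, 83.3%. Among the 92 calls, 2 were of probes that had not been shifted. When 1 list was shifted, camera called it and 1 list more. Simulated probes and genes varied independently of each other, while the estimated correlation in the real antigen presentation list was 0.89. The simulation therefore checks neither the preset correlation of camera nor false calls among correlated genes.

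Alternatives, set before the data were examined, were no background correction, cyclic loess or median scaling in place of quantile normalization, the authors' normalized values, other detection filters, the replicate number as a block, array weights, a trended and robust variance prior, other thresholds, one probe per gene, the mean over a gene's probes in the list test, other list tests, and leaving out each tumour in turn with the same probes and normalized values. A fit with the mean of the neuron list as a covariate and the folds with undetected values raised were added after the data had been seen. Slide as a block was not run, as no slide is named.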

Results

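Transcripts were measured on bead arrays in 6 brain tumours grown in SCID mice, which lack mature T and B cells. All tumours came from transplanted cells with floxed p53 alleles and the human EGFRvIII gene, which encodes a truncated, constantly active EGF receptor found in glioma. The 3 Olig2_het tumours carried cre at 1 Olig2 allele and kept the other, and the 3 Olig2_null tumours carried cre at both. Olig2 is a transcription factor of oligodendrocyte precursors and of many gliomas. The comparison asks how tumours with and without an intact Olig2 allele differ in gene expression once they cause symptoms. Between 53.4% and 57.6% of the 25697 probes were detected per array. Replicates correlated at r = 0.943 to 0.980 over tested probes among the Olig2_het tumours and at r = 0.886 to 0.928 among the Olig2_null tumours. Olig2_null replicate 3 stood apart from its group: it correlated at 0.886 and 0.928 with Olig2_null replicates 1 and 2, and at 0.941, 0.935 and 0.914 with Olig2_het replicates 1 to 3. On the first principal component (62.6% of the variance) it lay at 5, between the other Olig2_null tumours (104 and 61.4) and the Olig2_het tumours (-76.9 to -38.9).

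The 1 Olig2 probe (ILMN_2724709) read log2 intensities of 7.76, 7.85 and 7.13 in the Olig2_het tumours and 6.41, 5.86 and 6.44 in the Olig2_null tumours. The difference of -1.34 ± 0.30 (SE, n = 3 per group) missed the threshold (limma adjusted p = 0.0555), although the values of the groups did not overlap. It passed without Olig2_null replicate 3 (-1.44, adjusted p = 0.0423), and the adjusted p was up to 0.277 over the settings tried. The probe was detected on all 6 arrays. Whether it lies in the part of the gene that the cre allele removes is not known here, so it checks the genotype labels only in part. Adjacent Olig1, chosen after its value was seen, read 14.74 ± 0.10 in Olig2_het and 13.99 ± 0.60 in Olig2_null (SD, n = 3, adjusted p = 0.221). Pdgfra, the PDGF receptor of oligodendrocyte precursors, read 11.41 ± 0.48 and 10.92 ± 1.79 (SD, n = 3, adjusted p = 0.760), with single Olig2_null values of 11.44, 8.92 and 12.39. Without Olig2_null replicate 2 the Pdgfra difference was 0.51 in place of -0.49. The brightest mouse Egfr probe differed by 0.34 ± 0.44 (SE, adjusted p = 0.680), while the other probes of the gene differed by 1.43 (adjusted p = 0.0649) and 1.35 (adjusted p = 0.0555). Whether these probes also bind the human transgene is not known here.

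The largest rises in the Olig2_null tumours included genes of secreted and basement membrane proteins, and the largest falls included genes of hypothalamic neuropeptides and of the oligodendrocyte lineage. Mia, a secreted protein of melanoma and cartilage, rose from 7.07 ± 0.55 to 12.40 ± 0.39 (SD, n = 3), a 40.1-fold difference (adjusted p = 0.00433). Nid2, a basement membrane nidogen, rose 28.0-fold (adjusted p = 0.00433), and Srpx2, a secreted sushi-repeat protein, rose 34.2-fold (adjusted p = 0.0172). The G protein subunit gene Gna14 rose 28.3-fold and the calpain-like gene Capn6 25.7-fold. The thyroid hormone-binding crystallin Crym rose 26.1-fold and Fam180a 26.8-fold. Wfdc3 rose 47.1-fold and the hypoxia-induced carbonic anhydrase Car9 28.1-fold, each detected on 1 of the 3 Olig2_het arrays, and Mamdc2 rose 27.5-fold, detected on 2 of them. With undetected values raised to the lowest detected signal these folds were 36.6, 24.6 and 23.1. The other Car9 probes differed by 2.40 and 3.22 and did not pass (adjusted p = 0.149 and 0.0570).

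Pmch, the precursor of melanin-concentrating hormone made in the lateral hypothalamus, fell from 13.37 ± 0.28 in Olig2_het to 5.19 ± 0.52 in Olig2_null (SD, n = 3), a 291-fold difference (adjusted p = 0.000472), and was detected on 1 of the 3 Olig2_null arrays. Hcrt, which encodes the orexins, was 26.5-fold higher in Olig2_het (adjusted p = 0.0146) and Cartpt, a neuropeptide precursor, 20.9-fold (adjusted p = 0.0297), each detected on 1 Olig2_null array. Trh, Oxt and Avp, the precursors of thyrotropin-releasing hormone, oxytocin and vasopressin, were not detected in any Olig2_null tumour and were at least 21.6-fold, 18.2-fold and 12.6-fold higher in Olig2_het (adjusted p = 0.00433, 0.0165 and 0.0238). The homeobox gene Isl1 was at least 13.3-fold higher there (adjusted p = 0.00799), and the secreted-peptide gene Tafa4 at least 10.9-fold (adjusted p = 0.0146). These bounds depend on the processing. Over the other settings tried the smallest log2 differences were -2.53 for Trh, -2.37 for Oxt, -2.07 for Avp, -2.10 for Isl1 and -1.93 for Tafa4. Gpr17, a receptor of committed oligodendrocyte precursors, fell 47.5-fold (adjusted p = 0.0173). Opalin, a myelin membrane protein, fell 36.1-fold (adjusted p = 0.0173) and was detected on 1 Olig2_null array. With undetected values raised to the lowest detected signal, the folds were 240 for Pmch, 22.5 for Hcrt, 16.3 for Cartpt and 26.2 for Opalin.

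**Figure D1:**
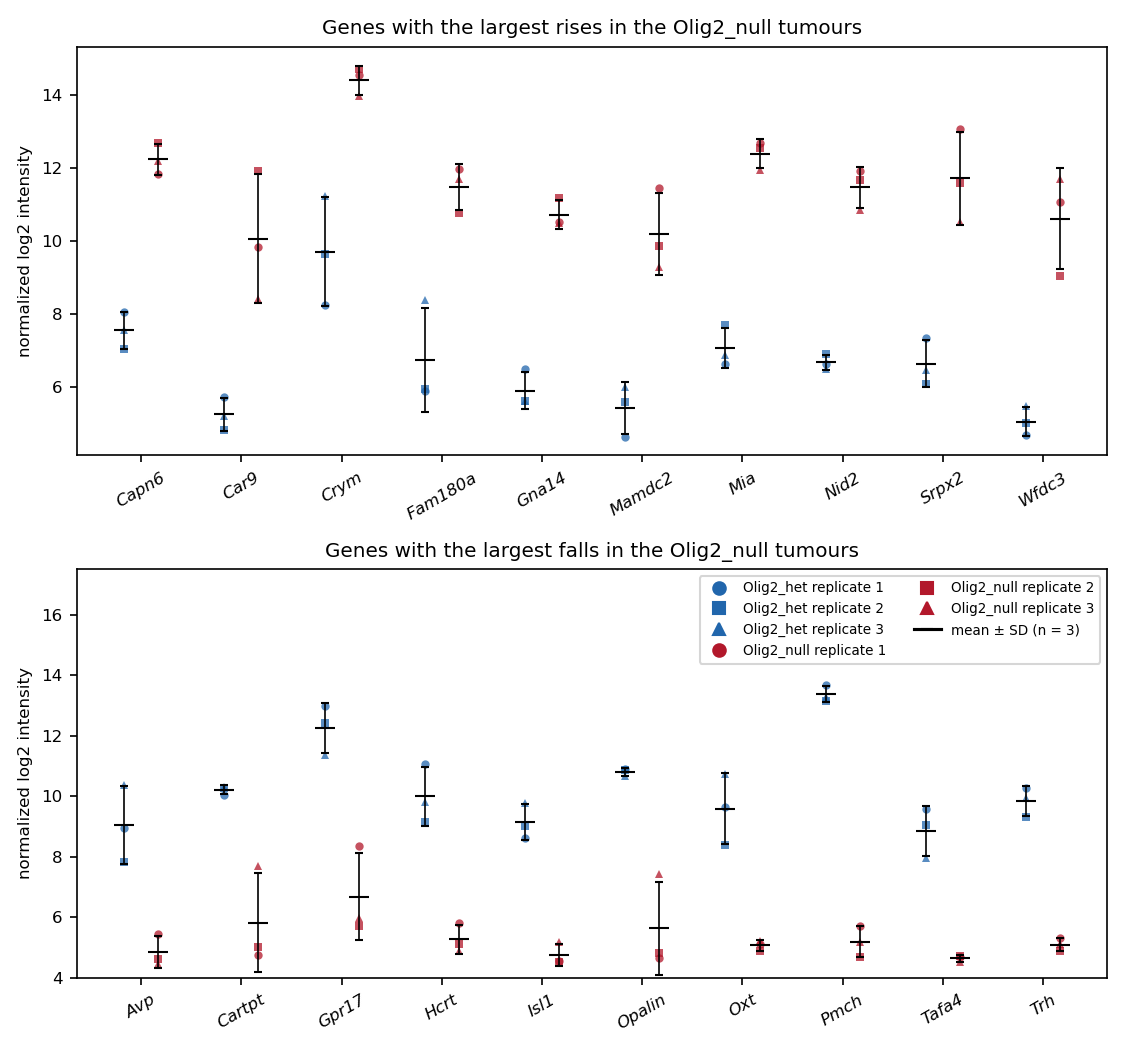
Normalized log2 intensity (vertical axis) of the 10 genes with the largest rises (top) and the 10 with the largest falls (bottom) in the Olig2_null tumours, in alphabetical order, with 1 point per tumour and the mean ± SD of each group. The groups do not overlap for any gene drawn, and Pmch reads 13.15 to 13.68 in the Olig2_het and 4.68 to 5.71 in the Olig2_null tumours.

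In all, 645 of 14606 tested probes passed (limma adjusted p under 0.05), 387 higher and 258 lower in Olig2_null, and they named 529 genes. The groups did not overlap for any of the 645. Over all tested probes 31.2% had no overlap, where chance gives 10% on average over the splits of the 6 tumours. Probes vary together, so the share in a single split can lie far from that average. Among the 645 probes, 33 were not detected on any Olig2_het array and 49 on any Olig2_null array. The count changed whichever tumour was left out: it was 10, 9 and 69 without Olig2_het replicates 1, 2 and 3, and 305, 116 and 1922 without Olig2_null replicates 1, 2 and 3. It was 398 with no background correction, 411 on the authors' normalized values, 230 with no detection filter, 1860 with array weights, 1382 with the replicate block, and 28 with the mean of the neuron list as a covariate. The balance depended on the setting too. The share of calls higher in Olig2_null was 60%, but 43.4% with the replicate block, 44.4% without Olig2_null replicate 3, 49.3% without Olig2_het replicate 3 and 48.3% at an unadjusted p under 0.05 (1787 higher and 1910 lower). Of 61 genes named here that passed, 8, 8 and 17 still passed without Olig2_het replicates 1, 2 and 3, and 47, 24 and 61 without Olig2_null replicates 1, 2 and 3. Mia, Gna14, Nid2 and Capn6 passed in all 19 other settings tried, and Pmch and Trh in the 18 that tested them, which leave out the setting with probes detected on all 6 arrays. Among these settings, the unadjusted threshold and the log2 difference of at least 1 could not end a call. The smallest called log2 difference was 1.08.

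Oligodendrocyte genes were lower in the Olig2_null tumours. Of 15 measured members of the oligodendrocyte list, 3 fell and 1 rose (11 did not pass; adjusted over the list alone, 10 fell and 1 rose), with a median difference of -3.10 and a camera adjusted p of 8.48e-05 (adjusted p = 0.663 with an estimated correlation). With the neuron list mean as a covariate the median was -1.19 (adjusted p = 0.0252). Beside Opalin, Enpp6, an early marker of myelinating cells, fell 13.9-fold (adjusted p = 0.0285) and Cnp, a myelin enzyme, 4.01-fold (adjusted p = 0.0411). The member that rose was Trf, the iron carrier transferrin, at 4.27-fold (adjusted p = 0.0291). Of 16 measured oligodendrocyte precursor genes, 3 fell and none rose (adjusted over the list alone, 8 fell), with a median of -1.11, or -0.93 with 2 members at their bound, and an adjusted p of 0.00145 (adjusted p = 0.712 with an estimated correlation). The precursor median was -0.58 with no background correction and -0.61 on the authors' values. The members that fell were Gpr17, Lims2, an adaptor of focal adhesions, at 9.77-fold (adjusted p = 0.0449), and Matn4, a matrilin of the matrix, at 4.48-fold (adjusted p = 0.0370). Gpr17 lies within the span of Lims2 on chromosome 18, so the calls of Gpr17 and Lims2 may not be separate evidence. One further probe of each of Lims2 and Matn4 did not pass (adjusted p = 0.0631 and 0.0927). The proneural glioma list shared 12 of its 15 measured members with other lists fixed here, Gpr17 among them. The precursor list shared 9 of 16, so their calls are not separate evidence. The proneural list had 2 members falling (adjusted over the list alone, 4) and a median of -0.79 (adjusted p = 0.00719, and adjusted p = 0.663 with an estimated correlation). Its other member past the threshold was Gabra3, a GABA receptor subunit, at 4.36-fold lower in Olig2_null (adjusted p = 0.0312).

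Neuronal markers moved with these groups. All 15 measured members of the neuron list were lower in Olig2_null, with a median of -2.71, although no member passed (adjusted over the list alone, 1 fell). The list's adjusted p was 8.48e-05, and the adjusted p was 0.712 with an estimated correlation. Snhg11 differed by -3.76 ± 0.85 and the synaptic vesicle gene Syt1 by -4.09 ± 1.16 (SE, adjusted p = 0.0564 and 0.0884). The list mean relative to the Olig2_het mean was -0.87, -0.04 and 0.92 in Olig2_het replicates 1 to 3 and -4.96, -2.36 and -0.86 in Olig2_null replicates 1 to 3. Olig2_null replicate 3 thus lay level with Olig2_het replicate 1, and without Olig2_null replicate 1 the median of the neuron list was -1.59. The mean of the oligodendrocyte list was -3.82, -3.29 and -0.91 in the Olig2_null tumours, and that of the precursor list -0.99, -1.88 and -1.25. The ependymal or choroid plexus list had no member past the threshold, a median of -1.32 and an adjusted p of 0.0473 (adjusted p = 0.760 with an estimated correlation), with Rsph1 at -1.32 and Enkur at -1.10 (adjusted p = 0.119 and 0.134). The ependymal list did not pass without Olig2_het replicate 2 or 3 (adjusted p = 0.0727 and 0.109) or without Olig2_null replicate 1 or 2 (median -0.83 and -0.76, adjusted p = 0.164 and 0.210). It did not pass with no background correction (-0.42, adjusted p = 0.0861), on the authors' values (-0.46, adjusted p = 0.0849) or with cyclic loess (adjusted p = 0.0540). With the neuron list mean as a covariate its median was 0.01 (adjusted p = 0.768). Astrocyte genes gave a median of 0.03 with none of 17 passing and a list adjusted p of 0.862, and Gfap, the astrocyte filament, differed by 1.63 ± 0.45 and Clu by -1.44 ± 0.37 (SE, adjusted p = 0.0860 and 0.0746).

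**Figure D2:**
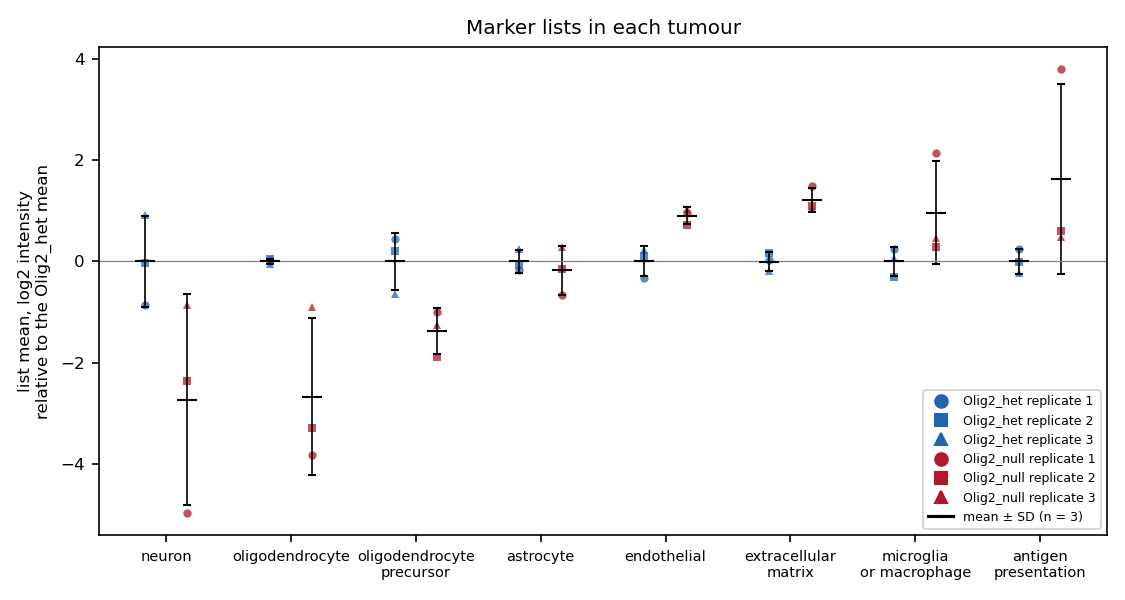
Mean log2 intensity of the measured members of 8 gene lists in each tumour, relative to the mean of the Olig2_het tumours (vertical axis), with 1 point per tumour and the mean ± SD of each group. The neuron and oligodendrocyte lists spread widely among the Olig2_null tumours (-4.96 to -0.86 and -3.82 to -0.91), while the extracellular matrix list lies between 1.06 and 1.48 in all 3 of them.

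Most measured genes of the extracellular matrix and of vessels were higher in the mean of the Olig2_null tumours. Of 20 measured matrix genes, 5 rose and none fell (15 did not pass; adjusted over the list alone, 9 rose and 1 fell), with a median of 1.34, or 1.16 with 2 members at their bound, and an adjusted p of 8.48e-05 (adjusted p = 0.663 with an estimated correlation). The proteoglycan gene Bgn rose 13.6-fold (adjusted p = 0.00557), the basement membrane collagens Col4a1 and Col4a2 7.37-fold and 7.11-fold (adjusted p = 0.0200 and 0.0173), and the laminin gene Lamc1 5.29-fold (adjusted p = 0.0267). Of 16 endothelial genes, 11 were higher and 5 lower in the mean of Olig2_null. The list had a median of 1.16 and an adjusted p of 0.000872 (adjusted p = 0.663 with an estimated correlation). Past the threshold, 4 endothelial genes rose (adjusted over the list alone, 6). They were Emcn at 8.33-fold and Pecam1 at 5.86-fold, which encode surface proteins of endothelium (adjusted p = 0.0146 for each), the receptor gene Tie1 at 3.05-fold, detected on 1 Olig2_het array (2.69-fold with undetected values raised, adjusted p = 0.0295), and the junction gene Esam at 2.96-fold (adjusted p = 0.0450). Of 9 pericyte or fibroblast genes, 1 rose, the pericyte gene Rgs5 at 6.57-fold (adjusted p = 0.0457; adjusted over the list alone, 7 rose), with a median of 1.21, or 1.13 with 1 member at its bound (list adjusted p = 0.00399, and adjusted p = 0.663 with an estimated correlation). The mesenchymal glioma list had 3 of 20 members rising (adjusted over the list alone, 6) and a median of 1.24, or 1.21 with 1 member at its bound (adjusted p = 0.000807, and adjusted p = 0.712 with an estimated correlation). Beside Col4a1 these were the annexins Anxa1, at least 2.38-fold higher and not detected in any Olig2_het tumour (adjusted p = 0.0173), and Anxa2, at 3.35-fold (adjusted p = 0.0424). The mesenchymal and matrix lists each shared 6 of 20 measured members with other lists, and Col4a1 was in both. Their calls are therefore not fully separate evidence. With no background correction the medians were 0.61 for matrix, 0.47 for endothelial, 0.51 for pericyte or fibroblast and 0.72 for mesenchymal genes. On the authors' values they were 0.65, 0.50, 0.54 and 0.75. The pericyte or fibroblast list did not pass among probes detected on all 6 arrays (adjusted p = 0.0534). With the neuron list mean as a covariate the matrix median was 0.67 and the mesenchymal median 0.43.

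Immune and signalling lists were also higher, with fewer members past the threshold. Of 17 microglia or macrophage genes, 2 rose, Ms4a7 14.1-fold and the lysozyme gene Lyz2 5.11-fold (adjusted p = 0.0467 and 0.0146; adjusted over the list alone, 2), with a median of 0.70 and a list adjusted p of 0.00399 (adjusted p = 0.760 with an estimated correlation). A further Lyz2 probe did not pass (adjusted p = 0.0580), and without Olig2_null replicate 1 the list's median was 0.14 (adjusted p = 0.178). With the neuron list mean as a covariate it was -0.23 (adjusted p = 0.802). All 15 antigen presentation genes were higher in the mean of Olig2_null, none passed, and the median was 1.53 (list adjusted p = 0.00175, and adjusted p = 0.760 with an estimated correlation). Tap2 differed by 1.88 and Psmb9 by 2.59 (adjusted p = 0.0911 and 0.137). The list mean was 3.79 above the Olig2_het mean in Olig2_null replicate 1 and 0.60 and 0.49 above it in replicates 2 and 3. Without replicate 1 the median of the antigen presentation list was 0.52 (adjusted p = 0.0171), and with the neuron covariate it was -0.47 (adjusted p = 0.253). The 5 neutrophil or monocyte genes gave a median of 1.23 with none passing (adjusted over the list alone, 2 rose; list adjusted p = 0.0413, and adjusted p = 0.663 with an estimated correlation). Plac8 differed by 2.70 and Lcn2 by 2.91 (adjusted p = 0.0525 and 0.0822). The neutrophil or monocyte list did not pass without Olig2_het replicate 2 or 3 or Olig2_null replicate 3 (adjusted p = 0.0727, 0.116 and 0.0797). Its median was 2.26 without Olig2_het replicate 1 and 0.69 without Olig2_het replicate 3. It did not pass with no background correction (0.66, adjusted p = 0.0779), on the authors' values (0.69, adjusted p = 0.0734), with no detection filter (0.23, adjusted p = 0.346) or with the neuron covariate (1.38, adjusted p = 0.111). Among 15 BMP and TGF-beta genes, 2 rose, the matrix signalling protein Ccn2 12.9-fold and the BMP target Id1 3.07-fold (adjusted p = 0.0282 and 0.0173; adjusted over the list alone, 4), with a median of 0.40 (list adjusted p = 0.0413, and adjusted p = 0.663 with an estimated correlation). In the MAPK response list Spry4, a feedback inhibitor of receptor kinase signalling, rose 6.39-fold (adjusted p = 0.0413), as 1 of 15 members (adjusted over the list alone, 4 rose and 1 fell), with a median of 0.67 (list adjusted p = 0.0413, and adjusted p = 0.760 with an estimated correlation). The classical glioma list, of which 10 of 13 measured members were also in other lists, gave a median of 0.47 with none of 13 passing (adjusted over the list alone, 3 rose; list adjusted p = 0.0302, and adjusted p = 0.663 with an estimated correlation). The Hedgehog transducer Smo differed by 1.37 (adjusted p = 0.0886), and Hs3st3b1 was not detected in any Olig2_het tumour and at least 2.02-fold higher (adjusted p = 0.0629). Leaving out a tumour also ended the calls of 3 more lists. The BMP and TGF-beta list did not pass without Olig2_het replicate 2 or Olig2_null replicate 2 (adjusted p = 0.0727 and 0.133). The MAPK list did not pass without Olig2_het replicate 3 or Olig2_null replicate 2 or 3 (adjusted p = 0.245, 0.0968 and 0.0797). The classical list did not pass without Olig2_het replicate 3 or Olig2_null replicate 3 (adjusted p = 0.184 and 0.0822). Without Olig2_het replicate 3 the MAPK median was 0.28, the classical median 0.19 and the BMP and TGF-beta median 0.66. Without Olig2_null replicate 3 the BMP and TGF-beta median was 0.86, and without Olig2_null replicate 2 the classical median was 0.74. Array weights ended the calls of the MAPK list (0.29, adjusted p = 0.145) and the classical list (0.22, adjusted p = 0.0831). The MAPK list was also lost among probes detected on all 6 arrays (adjusted p = 0.0518) and with the neuron covariate (0.35, adjusted p = 0.0551), and the BMP and TGF-beta list with no detection filter (0.34, adjusted p = 0.0842).

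Single genes passed in lists that did not. In the neuroblast list the interneuron homeobox genes Dlx2 and Dlx1 rose 13.9-fold and 13.6-fold (adjusted p = 0.0146 for each), while the median of its 11 measured members was -0.68, their mean 0.01, and the camera direction up (adjusted over the list alone, 3 rose and 2 fell; list adjusted p = 0.948). Among 14 regional patterning genes the midbrain and hindbrain gene En2 rose 23.6-fold (adjusted p = 0.00932) and Nkx2-1, a gene of the ventral forebrain and hypothalamus, fell 3.52-fold, detected on 1 Olig2_null array (3.18-fold with undetected values raised, adjusted p = 0.0289), with a median of -0.61 (adjusted over the list alone, 2 rose and 4 fell; list adjusted p = 0.325). The Wnt receptor gene Fzd1 rose 8.88-fold (adjusted p = 0.0146) and the Wnt target Lgr5, not detected in any Olig2_null tumour, was at least 1.76-fold lower there (adjusted p = 0.0472), in a list of 14 with a median of -0.12, a mean of 0.18 and an adjusted p of 0.860 (adjusted over the list alone, 3 rose and 2 fell). The endothelial Notch receptor gene Notch4 rose 3.49-fold (adjusted p = 0.0173), in a list of 15 with a median of 0.18 (adjusted over the list alone, 5 rose and 1 fell; list adjusted p = 0.265). Trp53inp1 rose 2.48-fold (adjusted p = 0.0291), with its other probe not passing (adjusted p = 0.136), as the 1 member of 17 p53 targets, whose median was 0.07 (adjusted over the list alone, 2 rose and 1 fell; list adjusted p = 0.511). Car9 was the 1 of 16 hypoxia and glycolysis genes to rise (adjusted over the list alone, 2; median 0.19, list adjusted p = 0.152). The hypoxia list passed without Olig2_null replicate 1 (0.29, adjusted p = 0.0183), and without Olig2_null replicate 2 its median was 0.01 (adjusted p = 0.901). Egr2, a zinc finger gene of the immediate early list, fell 5.99-fold (adjusted p = 0.0272), in a list of 12 with a median of -0.42 (adjusted over the list alone, 2 fell; list adjusted p = 0.124, and adjusted p = 0.0122 without Olig2_null replicate 2). Rcan1, a calcineurin inhibitor gene near Olig2, fell 2.34-fold (adjusted p = 0.0469) and was the 1 of 25 neighbours of Olig2 to pass, with its other probe not passing (adjusted p = 0.722) and a list median of -0.24 (adjusted over the list alone, 1 fell; list adjusted p = 0.158, and adjusted p = 0.0183 without Olig2_null replicate 1). Leaving out 1 tumour gave medians of 0.02 to 0.36 for Notch, -1.03 to -0.32 for patterning, -0.84 to -0.21 for neuroblast, -0.78 to -0.25 for immediate early genes and -0.44 to -0.17 for the neighbours of Olig2.

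No member passed by its representative probe in the remaining tested lists, also when adjusted over the list alone. Other probes passed for Cxcl12 of the cytokine list (2.85, adjusted p = 0.0436) and Mcm6 of the S phase list (-3.48, adjusted p = 0.0310), whose other probes differed by 0.06 and 0.03. Cell cycle genes gave medians of 0.11 over 11 genes of G2 and mitosis and 0.09 over 17 genes of S phase (list adjusted p = 0.392 and 0.562). The medians were -0.09 for neural stem or progenitor genes (list adjusted p = 0.862), 0.21 for receptor tyrosine kinases and their ligands (0.734), 0.78 for the interferon response (0.158), 0.51 for cytokines and chemokines (0.477), and -0.02 with a mean of 0.27 for glioma tumour suppressors and oncogenes (0.685). The interferon list mean was 2.05, -0.32 and 0.06 in Olig2_null replicates 1 to 3, and its median was 0.07 without replicate 1 and 1.13 without replicate 2, where it passed (adjusted p = 0.757 and 0.0114). Without Olig2_het replicate 1 the cytokine list and the list of G2 and mitosis passed (medians 0.95 and 0.38, adjusted p = 0.0442 for each). Lists with fewer than 5 measured members were not tested: the medians were -0.29 for lymphoid genes, 3.34 for the erythroid gene measured, 1.36 for Hedgehog genes and -0.30 for X-inactivation and Y-linked genes. That last median hides a spread. Xist (ILMN_3022688) read 8.55, 9.18 and 6.81 in Olig2_het replicates 1 to 3. It read 9.69, 9.05 and 4.63 in Olig2_null replicates 1 to 3, undetected in the last. Y-linked Eif2s3y was detected on all 6 arrays. The cause was not tested.

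Of the 31 lists tested, 15 passed with the preset correlation, 10 higher and 5 lower in Olig2_null. None passed with an estimated correlation, where the smallest adjusted p was 0.663, and 2 did with fry, which tests for movement on balance in one direction and does not compare a list with other genes (extracellular matrix and pericyte or fibroblast, adjusted p = 0.0467 for each).

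**Figure D3:**
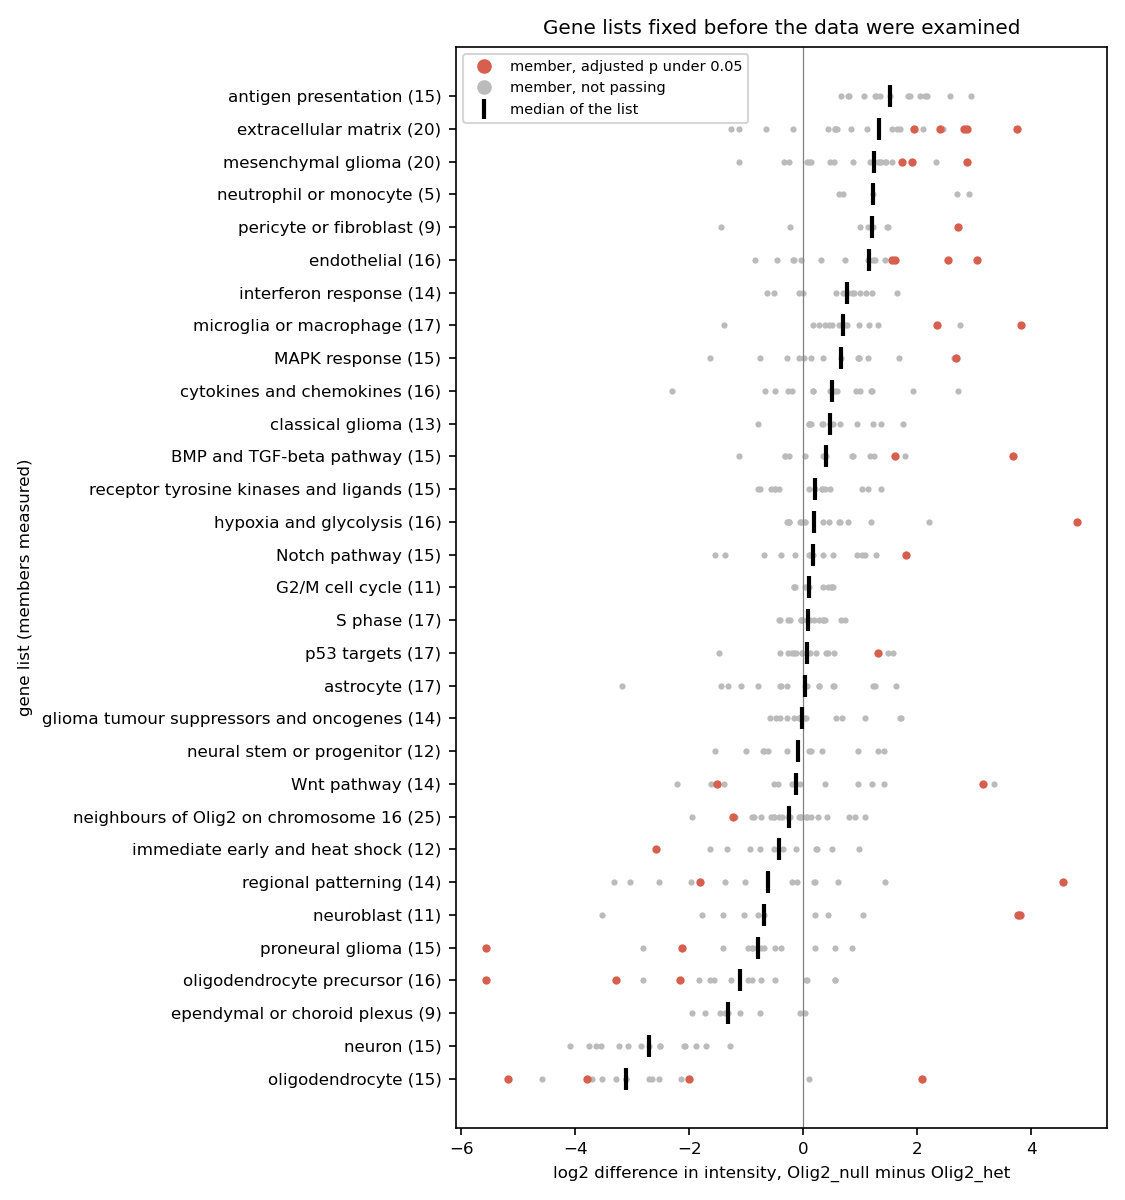
Log2 difference in intensity, Olig2_null minus Olig2_het (horizontal axis), of each measured member of the 31 tested gene lists, with members past an adjusted p of 0.05 in red and the median of each list as a black bar. The medians run from -3.10 for oligodendrocyte genes to 1.53 for antigen presentation genes.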

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

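The alternatives below were set before the data were examined, except the fit with the neuron list mean as a covariate, which was chosen after seeing the data. Signal close to background limits what can be seen: 8619 of 25697 probes were not detected on any array.

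The count of probes differing between Olig2_null and Olig2_het, 645, came to 592 with cyclic loess, 680 with median scaling, 472 among probes detected on all 6 arrays, 681 with the trended and robust prior, 645 with a log2 difference of at least 1, and 511 on representative probes. No call changed sign in any setting. The count fell to 398 with no background correction and 411 on the authors' normalized values, where 351 and 367 of the 645 were still called, and to 230 with no detection filter over 25697 probes. It rose to 1860 with array weights and was 3697 at an unadjusted p under 0.05. Leaving out 1 tumour gave 9 to 1922. With the covariate 28 probes passed, 23 of them among the 645, in a fit with 1 residual degree of freedom fewer. The share of calls that were higher in Olig2_null was 60% and lay between 56.9% and 61.8% under the other scalings and background settings, at 70.1% among probes detected on all 6 arrays, at 43.4% with the replicate block and at 44.4% without Olig2_null replicate 3. For the other counts the cause was not tested.

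Replicate numbers were not treated as pairs. The deviations of same-numbered tumours from their group means correlated at 0.19, 0.02 and 0.30, and Olig2_het replicate 2 correlated more with Olig2_null replicate 1 (0.07) than with its own number. Between groups, tumours of different numbers correlated at -0.30 to 0.10, so numbers 1 and 3 lay above all of these. A pairing by number is therefore not excluded. With the replicate block the count of probes differing between Olig2_null and Olig2_het was 1382, 600 higher and 782 lower, 618 of the 645 were still called, and 16 lists passed. Of 25 named genes that did not pass in the main fit, 9 passed with the block, among them Snhg11, Syt1 and Tap2.

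The count of 15 lists stayed between 11 and 17 under the other settings, leave-outs included, except that it was 0 with an estimated correlation and 2 with fry. Different lists were lost, as given beside each. The interferon list passed with the replicate block (0.0418) and the Notch list on probes detected on all 6 arrays (0.0286). The covariate is the mean of the neuron list, so that list's median went to 0.08 by construction. It ended the calls of the microglia (median -0.23), ependymal (0.01) and antigen presentation (-0.47) lists and turned their medians, and ended those of the neutrophil or monocyte and MAPK lists. Among lists that had not passed, the medians with the covariate were 0.09 for neuroblast, -0.08 for G2 and mitosis, -0.25 for S phase, -0.80 for interferon genes, which then passed as lower (adjusted p = 0.00377, against 0.00377 to 0.865 over all settings), and -0.81 for cytokine genes. The hypoxia list (0.34, adjusted p = 0.0255) and the neighbours of Olig2 (-0.59, adjusted p = 0.0048) also passed with it. Array weights gave -0.04 for G2 and mitosis and -0.26 for S phase. With no detection filter the medians were -0.18 for astrocyte, 0.05 for stem, 0 for receptor kinase and 0.01 for patterning genes. On probes detected on all 6 arrays they were 0.10 for stem, 0.21 for neuroblast and 0.18 for patterning genes. Stem genes gave 0.06 with no background correction and 0.06 on the authors' values, and oncogenes 0.01 with median scaling. Leaving out 1 tumour gave medians of -0.09 to 0.07 for astrocyte, -0.52 to 0.25 for stem, -0.20 to 0.38 for G2 and mitosis, -0.26 to 0.34 for S phase, -0.04 to 0.10 for p53, -0.25 to 0.42 for receptor kinase, -0.12 to 0.05 for Wnt, -0.18 to 0.95 for cytokine, 0.07 to 1.13 for interferon and -0.21 to 0.10 for oncogene lists. For these the cause was not tested.

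Olig2 stayed lower in Olig2_null under all 19 alternatives (-1.57 to -0.59) and passed in 3 of them: with array weights (-1.57, adjusted p = 0.0153), at an unadjusted threshold (-1.34) and without Olig2_null replicate 3 (-1.44). Its largest adjusted p was 0.277, with the covariate. Leaving out 1 tumour gave -1.57 to -1.16. The cause was not tested. Pdgfra ran from -1.23 to 0.51 over the leave-outs. The representative Mcm6 probe (0.06) read -0.30 with array weights, -0.25 with the covariate and -0.39 to 0.29 over the leave-outs; Nnat (0.46) 0 to 0.88 over the leave-outs, none of them passing. Pvalb (-2.89) read 2.39 with the covariate, not passing, and passed only without Olig2_null replicate 3 (-5.38). The cause was not tested. Of 61 called genes that are named, none changed sign. With the covariate 13 still passed.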

Other observations

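The genes named in this part were chosen after their values were seen, and the tests here were chosen then too, except the tests of further hypothalamic and cerebellar genes, which were written before those genes were looked at. Among single genes with no list or enrichment test behind them, Stat5a rose 7.53-fold in Olig2_null, and Cish and Socs2, known targets of STAT5, rose 7.27-fold and 3.66-fold (limma adjusted p = 0.0146, 0.0146 and 0.0324), with Stat5a detected on 2 of the 3 Olig2_het arrays (7.52-fold with undetected values raised) and its other probe not passing (adjusted p = 0.0957). The cell cycle inhibitor Cdkn1c rose 15.0-fold (adjusted p = 0.0146), Mest 6.36-fold (adjusted p = 0.0310) and Igf2r 2.84-fold (adjusted p = 0.0334), with the other Igf2r probe not passing (adjusted p = 0.0910). These 3 are imprinted genes. Of other imprinted genes, Dlk1 differed by 2.44, Nnat by 0.46, Peg3 by -1.16 and Ndn by -1.77 (adjusted p = 0.220, 0.574, 0.157 and 0.140).

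Dhh, a Schwann cell ligand, rose 22.5-fold, Gldn, a glial protein of nerve nodes, 8.09-fold, and Tfap2a, a neural crest transcription factor not detected in any Olig2_het tumour, at least 12.5-fold (adjusted p = 0.0231, 0.0291 and 0.0172), beside Mia. The other Tfap2a probes did not pass (adjusted p = 0.0911 and 0.249), and the smallest Tfap2a difference over the other settings was 1.98. A Schwann cell or neural crest programme was one hypothesis. The median difference over 17 other genes of those cells was -0.27 (95% bootstrap interval over genes -1.04 to 0.38), 10 of them lower and 7 higher, which gives it no support. A median under 0.5 with an interval below 1 had been set as evidence against it, but the members went both ways, with Ngfr at 4.59 (adjusted p = 0.0702), so that bound was wrong for a programme shared in part and the test decides little. No technical explanation was tested for these genes.

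Pmch, Trh, Oxt, Avp and Hcrt were near background in the Olig2_null tumours, while the neuropeptide genes Gal (10.47, against 9.41 in Olig2_het) and Pdyn (7.89, against 10.50) were detected in all 3 of them, and Pcp2, a Purkinje cell gene, read 12 in Olig2_null replicate 3 and at most 4.75 in the other tumours, where it was not detected. A smaller share of host neurons of any region in the Olig2_null samples was tested on the 12 hypothalamic genes seen first, 11 of them lower. With the neuron list mean in the fit their median was -3.31 (95% interval over genes -4.69 to -1.43, against a median of -4.30 without it). Their mean in that fit was -3.31 (over tumours -4.84 to -1.77). These genes thus stayed lower in that fit. They include some of the largest falls named above, such as Pmch, Trh and Hcrt, so a test on them cannot exclude fewer neurons. The other test was written before its genes were looked at. There the median of 14 further hypothalamic genes lay above that of the neuron list by 1.41 (0.08 to 3.31), as fewer neurons would allow. But these genes went both ways, from -3.59 for Resp18 to 2.44 for Dlk1, and 9 were detected in all 3 Olig2_null tumours. That comparison therefore decides little. Hypothalamic host tissue in the Olig2_het samples remains possible and may add to the signal of these genes. The 14 further genes had a median of -1.30 (-2.61 to 0.46) and 64.3% were lower; an interval that includes 0 had been set as evidence against it, but it spans -2.61 as well, and 9 of the 14 genes were detected in all 3 Olig2_null tumours, so the test decides little. Genes of the cortex and the striatum had medians of -1.82 over 10 genes and -2.06 over 9, with 9 lower and 1 passing in each. Lower values were thus not confined to hypothalamic genes, but the regions differed over tumours. Relative to the Olig2_het mean, striatal medians per tumour overlapped, at -1.44 to 1.57 in Olig2_het and -3.18 to -1.03 in Olig2_null. Cortical medians were -1.29 to 1.16 and -2.27 to -1.41. Those of the 12 hypothalamic genes seen first were -0.38 to 0.33 and -4.51 to -3.23. Cerebellar host tissue in Olig2_null replicate 3 also stays open, with a median excess of 1 over 9 further cerebellar genes (0.54 to 3.00), where an excess above 1 had been asked for, while Pvalb read 14.09 there and 12.70 in Olig2_het replicate 3, and genotype itself was not tested.

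Oligodendrocyte lineage genes were lower in the Olig2_null tumours together with neuronal genes, and less host brain in those samples was tested as an explanation. For the precursor list the values go against it as the whole cause: with the neuron list mean in the fit the median went from -1.11 to -1.63 (95% bootstrap interval over genes -2.95 to -0.46), and Olig2_het replicate 1 and Olig2_null replicate 3, level in the neuron list at -0.87 and -0.86, had precursor means of 0.44 and -1.25. It is not excluded, because the interval over tumours of the list mean, -1.85 with the neuron list in the fit and -1.37 without it, ran from -3.74 to 0.03 with 3 residual degrees of freedom. For the mature list the median went from -3.10 to -1.19 (-1.62 to 0.25 over genes), and the list mean from -2.67 to -1.19 (-4.09 to 1.71 over tumours), so the genotype and host brain cannot be told apart for it. Gpr17 and Matn4 still passed in that fit, at -7.40 and -3.05 (limma adjusted p = 0.0170 and 0.0404), while Lims2, Opalin, Enpp6, Cnp and Trf did not.

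Most extracellular matrix genes were higher in the Olig2_null tumours. Less host brain there was tested on the assumption that it raises all other genes alike. The matrix median exceeded that of the cell cycle lists by 1.24 (95% interval over genes 0.36 to 1.93). That goes against less host brain as the whole source only under this assumption, which was not tested, and the interval does not cover the spread between tumours. Less host brain may be part of the source: with the neuron list mean in the fit the matrix median went from 1.34 to 0.67 (0.36 to 1.69 over genes). The list mean went from 1.21 to 0.91 (0.43 to 1.38 over tumours) and so stayed above 0 in that fit. More vessels in the Olig2_null samples remain a candidate source, since the endothelial median minus the matrix median was -0.18 (-1.52 to 0.68). Of the endothelial genes, 11 were higher and 5 lower in Olig2_null. Matrix made by the tumour cells themselves was not tested.

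The 10 splits of the 6 tumours into 3 and 3 are too few for a share under 0.05. The genotypes gave 645 probes and the highest other split 0, so 1 of 10 splits, the real one, gave as many. For the lists the genotypes gave 15 and the highest other split 15, so 2 of 10 gave as many, and no split gave under 6.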
